A study of Mus musculus with 24 samples.

How the data were processed

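Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on V6.5 mouse embryonic stem cells, either growing asynchronously or collected in mitosis. Per the labels, mitotic cells were detached by shaking after 7 h of nocodazole, a drug that blocks spindle assembly, given as 100 ug/ml, a dose far above common use that may be an error of unit in the labels. Cells were fixed in 1% formaldehyde for 10 min and libraries were read as single ends of 50 nt. The antibodies were against Klf4 (R&D AF3158), Oct4 (Santa Cruz SC-8628), Sox2 (R&D AF2018) and acetylated lysine 27 of histone H3, H3K27ac (Abcam ab4729). The 24 samples held 17 libraries with a peak list and 7 inputs, which had no list of their own. Among the 17 was a Klf4 library from a mix of 10% embryonic stem cells and 90% neural progenitors.

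Per the submitters' processing notes, reads were trimmed with cutadapt 1.8.1 and aligned to mm10 with Bowtie2 2.2.5, coverage was made with deepTools 2.3.6, and peaks were called with MACS2 2.1.1. Each deposited narrowPeak file listed the peaks of 1 library. In these deposited lists the enrichment of a peak was a fold (a ratio of signal to local background), and the authors gave its p and q as −log10 values. Every listed peak had a −log10 p of at least 5, summit positions were absent, and gaps in the numbers within peak names showed that between 0.920% and 67.3% of the numbered peaks were listed. Read depth was not given, so the depth behind each peak was unknown, and the length of a list was the only measure of yield per library. Intervals given for percentages and odds ratios cover counting error only.

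Lists were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, tested with scipy 1.17.1 and statsmodels 0.14.6, and drawn with matplotlib 3.10.9. For each antibody all peaks of the stem cell libraries were merged where they shared at least 1 bp. A merged region entered the asynchronous set when at least 2 of 3 asynchronous libraries (Klf4), both (H3K27ac) or the single library (Oct4, Sox2) had a peak in it. Such a region was called kept when at least 2 mitotic libraries also had a peak in it, lost when no mitotic library did, and intermediate otherwise. Mitotic-only regions had a peak in at least 2 mitotic libraries and in no asynchronous library. Where runs without a library left only 1 of a state, a peak in that library sufficed. Where they left 2 of 3 (Klf4), both had to have a peak. Recovery was the percent of the asynchronous set with a peak in a given mitotic library. The overlap to be had by position alone was measured with 100 circular shifts within chromosomes. Lists of equal length held the strongest peaks by the deposited −log10 p, as many as in the shortest list of the antibody. Strength was the percentile of a region's fold within its asynchronous lists.

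Genes came from an mm10 (GRCm38.p6) table of 21887 protein-coding genes without strand. Distances were therefore taken to either end of the gene span in place of the transcription start, and from the region midpoint in place of the summit. Genome sequence was not used here, and the planned motif and base composition tests were not run. A region near a gene end had its nearer edge, not its midpoint, within 1 kb of one. Other features were scored by overlap of at least 1 bp anywhere in the region. Kept regions had larger median widths than lost ones: 586 against 336 bp (Klf4), 494.5 against 239 (Oct4), 431 against 162 (Sox2) and 1952.5 against 841 (H3K27ac). Wider regions can meet a feature more often by construction. Features of kept and lost regions were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment per antibody, and again within 5 quintiles of strength (Mantel-Haenszel). The 11 gene lists were naive pluripotency, primed pluripotency, germ layer regulators, neural progenitor, feeder fibroblast, mitotic cell cycle, G1 and S phase, housekeeping, glycolysis and energy, LIF Wnt and Bmp signalling, and chromatin regulators. Some genes were in more than 1 list (Jarid2, Il6st, Lifr, Stat3, Socs3, Lef1, Cdx1, Gapdh, Pgk1 and Gpi1). All 336 genes of the lists were in the table. A gene was bound when an asynchronous region lay within 20 kb of a gene end, and counted as kept when at least 1 such region was kept. A region within 20 kb of several genes counted for each of them, also in numbers of linked regions. Lists were compared with all other bound genes by two-sided Fisher's exact test, adjusted over the 11 lists per antibody, and with 10000 random lists matched on the decile of the strongest linked region. Differences between libraries were tested with exact two-sided permutation tests, whose smallest possible p was 0.1 for 3 against 3 or 3 against 2 libraries and 0.333 for 2 against 2. The test on pairwise overlap of Klf4 lists was in a single direction. It counted only splits whose overlap within minus between groups was at least as large as the real one.

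Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Per antibody, the rule took the genes nearest to the 10 kept and the 10 lost regions of highest strength and to the 5 mitotic-only regions of highest strength, within 50 kb and for regions of at most 10 kb. For Klf4 these regions had to be present in all 3 libraries of their state. It also took the naive pluripotency genes with an asynchronous region and a few members of the other lists. Some genes that the rule or the lists took are not reported here. Alternatives were a −log10 q of at least 5, an overlap of at least 50% of the shorter interval, a single mitotic library as the requirement, lists of equal length, gene windows of 2 and 50 kb or a gene end window of 5 kb, ranking by −log10 p, and leaving out each library in turn. Chosen after the data were seen were runs without chromosome 8, without both Klf4 libraries of project EC-DG-3514, with features measured at the region midpoint, with lists matched on strength and number of regions, and with Klf4 features within project EC-EA-3702 alone.

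File labels carry project codes, treated here as possible batches. Project EC-EA-3702 held Klf4 asynchronous 3, Klf4 mitotic 3 and all Oct4 and Sox2 libraries; Klf4 mitotic 1 and 2 and both H3K27ac mitotic libraries were of project EC-DG-3514, both H3K27ac asynchronous libraries of project EC-DG-3458, and Klf4 asynchronous 1 and 2 of projects EC-EA-2697 and EC-EA-2643. For H3K27ac, state and project coincided. Peak names in Oct4 mitotic 1 end in L2_2 and those in Oct4 mitotic 2 in L2_1, so these numbers may be crossed, and the labels were followed. Labels do not say whether replicates were separate cultures, so p-values across libraries measure the spread between these samples, and regions or genes within a library are not independent replicates. The calculation was tested on simulated data: a planted odds ratio of 2 over 29460 regions came back as 2.03 (95% interval 1.93 to 2.14), 0 of 4 features without an effect were called, and of 200 random gene lists 4.5% were called against 100% of the planted lists. In the simulation all libraries of a state held the same regions, and strength was unrelated to retention. It thus did not test the effects of list length, strength or spread between libraries. Its gene lists held more bound genes than most of the real ones. Input libraries and coverage tracks were not used here.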

Results

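The deposited data comprised peak lists for 3 pluripotency transcription factors and an active chromatin mark in mouse embryonic stem cells, in asynchronous culture and in mitosis. Klf4 was profiled in 3 asynchronous and 3 mitotic libraries and in 1 library of a 10% stem cell mix. Oct4 and Sox2 each had 1 asynchronous and 2 mitotic libraries, and H3K27ac had 2 of each. Klf4 (a zinc finger factor), Oct4 (a POU factor encoded by Pou5f1) and Sox2 (an HMG box factor) maintain pluripotency, and H3K27ac marks active promoters and enhancers. The series concerns which regulatory elements stay marked through mitosis, when most transcription stops. Coordinates are 1-based mm10 positions.

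Fewer Klf4 peaks were listed for mitotic than for asynchronous stem cells, at unknown read depth. The lists held 16112 ± 5374 peaks in asynchronous cells (SD, n = 3; 10575, 21307 and 16455) and 5996 ± 2331 in mitotic cells (SD, n = 3; 5754, 3795 and 8438). This was a log2 change of −1.44 with no overlap between the groups (exact permutation test, p = 0.1, the smallest possible with 3 against 3). Within project EC-EA-3702, the only project with Klf4 in both states, the number went from 16455 to 8438, and without both Klf4 libraries of project EC-DG-3514 the log2 change was −0.88. With −log10 q of at least 5 the log2 change was −3.13. The Klf4 lists held 50.0%, 61.4% and 67.3% of the numbered peaks in asynchronous and 23.6%, 7.17% and 51.5% in mitotic libraries, and the highest peak number of these 6 libraries, 52917, was in mitotic 2. H3K27ac lists held 46983 ± 696 peaks in asynchronous (SD, n = 2; 47475 and 46491) and 36526 and 30771 in mitotic cells. Oct4 and Sox2 did not share such a fall across their libraries: Oct4 had 3347 asynchronous peaks against 1246 and 5282 in mitosis, and Sox2 had 2986 against 4537 and 1940. Median fold enrichment per library lay between 3.29 and 6.03. Peaks with q above 0.05 made up 22.5% of the Sox2 mitotic 2 list, 9.47% of Oct4 mitotic 1, 3.18% of Sox2 asynchronous and 2.40% of Klf4 mitotic 2.

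**Figure D1:**
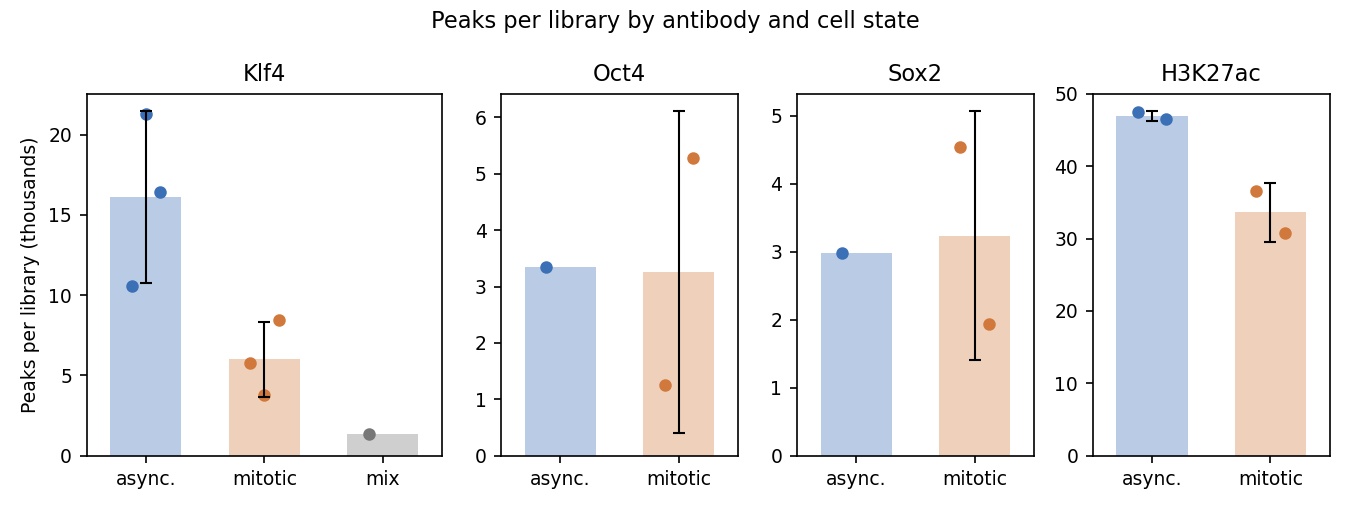
Number of listed peaks per library (vertical axis, in units of 1000; bars are group means, dots libraries, error bars SD) for each antibody in asynchronous and mitotic cells and, for Klf4, in the 10% mix; each panel has its own axis. All 3 mitotic Klf4 libraries lay below the lowest asynchronous one (10575 peaks), whereas the pair of mitotic Oct4 and of mitotic Sox2 libraries lay on both sides of their asynchronous library.

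The question of which Klf4 sites stay occupied in mitosis was addressed by overlap. Kept Klf4 regions included some by genes of the pluripotency network: Nanog, a core pluripotency factor, had a kept region 4.70 kb from the gene (chromosome 6, 122702329 to 122703260), with folds of 9.83, 7.50 and 9.99 in asynchronous and 6.92, 5.39 and 9.08 in mitotic libraries. Kept regions were also found by Pou5f1 (chromosome 17, 35516699 to 35517395), inside Esrrb, an orphan nuclear receptor of naive cells (chromosome 12, 86501408 to 86502123), inside Tbx3 (chromosome 5, 119681778 to 119682264), and by Klf2, a related Klf factor. Of 92 Klf4 regions linked to naive pluripotency genes 40 were kept and 24 lost, and lost ones lay by Pou5f1 and Tbx3 as well. Of 13982 asynchronous Klf4 regions, 3758 (26.9%, 95% Wilson interval 26.1 to 27.6) were kept, 4068 (29.1%) were found in a single mitotic library and 6156 (44.0%) in none. Only 97 regions were mitotic-only, 2.33% of the 4155 regions with a peak in at least 2 mitotic libraries. This balance depended on list length: with lists of equal length 1539 of 3235 Klf4 regions were kept, 832 lost and 491 mitotic-only. The kept share also fell with −log10 q of at least 5 and rose when any mitotic library sufficed. Single mitotic libraries recovered 30.3%, 18.9% and 44.2% of the asynchronous regions (31.1% ± 12.7, SD, n = 3), against 0.192%, 0.101% and 0.308% after circular shifts.

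The strongest kept Klf4 region lay 33.0 kb from Grap, a Grb2-related adaptor (chromosome 11, 61619814 to 61620869), with folds of 48.3, 18.0 and 49.8 in asynchronous and 10.6, 11.5 and 28.2 in mitotic libraries. The other kept regions of highest strength lay by Lrrc26, Map3k6 (a MAP kinase kinase kinase; chromosome 4, 133250428 to 133251532), Ass1 (argininosuccinate synthase; chromosome 2, 31469762 to 31470390), Prph, the tyrosine kinase gene Src (chromosome 2, 157456908 to 157457942), Uspl1, Fbxo15 (a marker of embryonic stem cells, 0.019 kb from the gene; chromosome 18, 84933893 to 84935173), Klhdc8a and Adh5. Lost regions of highest strength lay by Myo15, an unconventional myosin of the inner ear (strength percentile 95.3), and by Cldn4, a tight junction claudin (chromosome 5, 134945185 to 134945685, with folds of 15.8, 7.76 and 9.30 in asynchronous cells). They also lay by Phyhip, Fbxw8, Sipa1l3, Slc35g1, Igip, Phf12, the polarity gene Pard6b and Amotl2 (percentile 87.8). Mitotic-only regions in all 3 mitotic libraries lay by Arl14epl, Syt5 and Rab11fip4, and 0 of these 3 stayed mitotic-only with peaks of −log10 q of at least 5. Leaving out a Klf4 library also tightened the rule, since both libraries left of that state then had to have a peak. The kept share was 43.3% without Klf4 asynchronous 2, 13.7% without mitotic 1 and 13.0% without mitotic 3, with 2726, 1921 and 1822 kept regions. The effect of a library was thus not separated from that of the rule. Lost regions numbered 3900 without asynchronous 1, 1632 without asynchronous 2 and 3430 without asynchronous 3, and mitotic-only regions numbered 241, 238, 30, 49 and 28 without asynchronous 2, asynchronous 3, mitotic 1, mitotic 2 and mitotic 3.

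Among Oct4 sites, those kept in mitosis included regions by Oct4's own gene and its partners. The region 1.99 kb from Pou5f1 (chromosome 17, 35503693 to 35504397) had a fold of 15.7 in asynchronous and 6.15 and 12.2 in mitotic cells, and that by Sox2 (chromosome 3, 34653690 to 34654416) 31.9 in asynchronous and 7.54 and 16.6 in mitotic cells. A kept Oct4 region lay 0.053 kb from Nanog (chromosome 6, 122707229 to 122707643). The strongest lay inside Abca4, a retinal transporter (chromosome 3, 122145154 to 122146102; fold 56.8 in asynchronous cells), followed by regions by Prr5, Ndufa4l2, Lemd1, Rnf169, Rapgef1, Mttp, Crlf2, the DNA demethylase gene Tet2 (chromosome 3, 133524331 to 133525254) and Vamp1. The Tet2 region lay 20.3 kb from a gene end, past the 20 kb window, so it did not count for Tet2 in the gene lists. Lost Oct4 regions of highest strength lay by Stmn2, a neuronal microtubule regulator (chromosome 3, 8509297 to 8509740; percentile 92.0), Tspan11, Tmem213, Gm8439, Sec23a, Gm31255, Btd, Rbbp8 and Slc13a2 (86.8), and mitotic-only ones by Slc18b1, Adra1a, Tbx20, Smim31 and Pdgfc. Of 3338 asynchronous Oct4 regions 820 (24.6%, 23.1 to 26.1) were kept and 1207 (36.2%) lost, and 294 were mitotic-only. Recovery was 25.7% in mitotic 1 and 62.7% in mitotic 2 (numbered as labelled, while peak names give the opposite order), against 0.0261% and 0.160% after shifts. Without mitotic 1, when a peak in mitotic 2 sufficed, kept and mitotic-only regions numbered 2093 (62.7%) and 3182. Without mitotic 2, lost regions numbered 2488.

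Sox2 sites kept in mitosis included the region 1.60 kb from the Sox2 gene (chromosome 3, 34653873 to 34654256), with folds of 21.1 in asynchronous and 15.9 and 12.4 in mitotic cells, and a region by Il6st, the signalling chain of the LIF receptor (chromosome 13, 112462327 to 112462981; 20.3 in asynchronous, 13.5 and 11.2 in mitotic cells). The Abca4 region was kept for Sox2 as well (chromosome 3, 122145229 to 122145823), as were strong regions by Rims2, Apol7a, Gm6871, the Klf family gene Klf9, Gm21992, Cpne5 and Fblim1. Lost Sox2 regions of highest strength lay by Zscan10, a zinc finger gene of embryonic stem cells (chromosome 17, 23601326 to 23601557; percentile 89.3), by Sox11, a factor of neuronal differentiation, and by Gm31255, Msra, Fscb, Tnfrsf17, Tspan11, Impa2 and Arl4a (82.5), and mitotic-only ones by Eps8, Pdk1, Fgd4, Ldhd and Dido1. Of 2972 asynchronous Sox2 regions 1217 (40.9%, 39.2 to 42.7) were kept and 845 (28.4%) lost, and 422 were mitotic-only. Recovery was 69.1% in mitotic 1 and 43.4% in mitotic 2, against 0.125% and 0.0441% after shifts. Without mitotic 2, when a peak in mitotic 1 sufficed, kept and mitotic-only regions numbered 2053 (69.1%) and 2484. Without mitotic 1, lost and mitotic-only regions numbered 1692 and 645.

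The strongest H3K27ac regions kept in mitosis lay by genes of varied function, among them Eif5a (translation), Srsf6 (splicing), Nucks1, Kansl1 and Dido1 (chromatin), Bicral, Ypel4, Ptpdc1 and Lpxn. Lost regions of highest strength lay by Ascc2 (percentile 95.6), Pole4, Galnt2, Vps35l, Ttc23l, Nt5m, Nwd1, the laminin gene Lamc1, Ube2v2 and the stem cell gene Tcl1 (91.4). The lost region by Tcl1 lay 36.2 kb from the gene, which also had a kept H3K27ac region within 20 kb. Mitotic-only regions of highest strength lay by Zeb1, a repressor that drives epithelial to mesenchymal transition (chromosome 18, 5784370 to 5792018), Zfp61, Mup20, the Polycomb gene Eed and Sec11a. Of 32482 asynchronous regions 14962 (46.1%, 45.5 to 46.6) were kept and 12803 (39.4%) lost, and 5781 were mitotic-only, 26.7% of the 21652 regions in both mitotic libraries. With lists of equal length 6378 of 23018 H3K27ac regions were lost and 6401 were mitotic-only. Recovery was 55.7% and 51.0% (53.3% ± 3.35, SD, n = 2), against 3.57% and 3.25% after shifts. Asynchronous and mitotic H3K27ac libraries came from different projects, so state and project could not be separated. Lost regions numbered 21044 without asynchronous 1 and 22427 without asynchronous 2 and mitotic-only ones 11114 without mitotic 2, where in each case a peak in the 1 library left of that state sufficed.

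**Figure D2:**
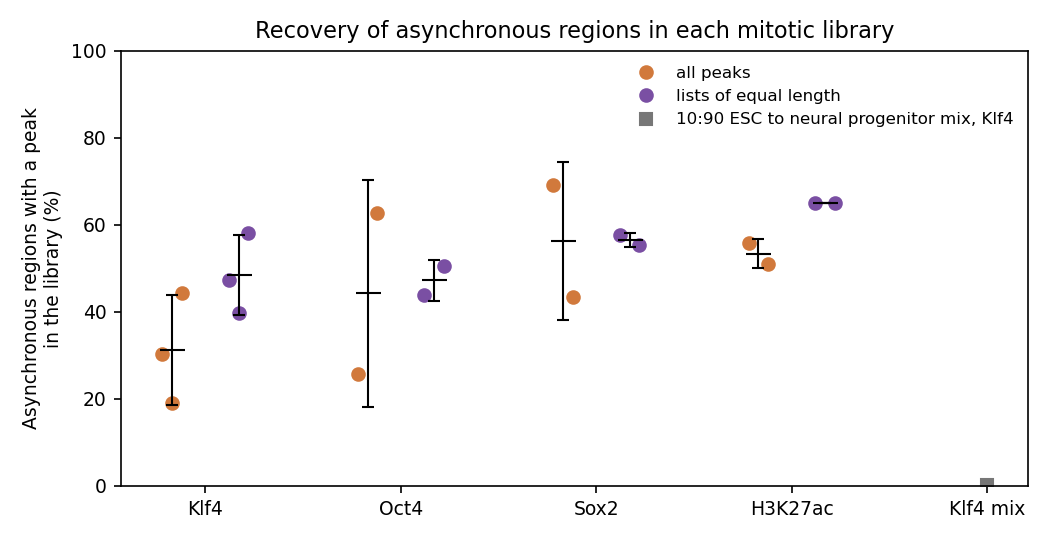
Percent of asynchronous regions with a peak in each mitotic library (vertical axis), per antibody, with all peaks (orange) and with lists of equal length (purple); dots are libraries, bars mean and SD, and the square is the Klf4 mix. Recovery by single Klf4 libraries ran from 18.9% to 44.2% with all peaks, and the mix stood at 0.0930%.

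How far the absence of Klf4 peaks in mitosis exceeded the difference between asynchronous libraries was asked with regions shared by 2 asynchronous libraries. The third asynchronous library recovered 72.0% ± 19.6 (SD, n = 3; 55.8%, 93.8% and 66.5%) of these Klf4 regions, and mitotic libraries 39.4% ± 14.7 (SD, n = 3; 39.1%, 24.9% and 54.3%). The difference of −32.6 percentage points gave p = 0.1 (exact two-sided permutation test, the smallest possible). With lists of equal length the Klf4 values were 67.9% ± 15.6 and 58.2% ± 10.5 (SD, n = 3 each; exact permutation p = 0.4). In pairs of equally long lists (3795 peaks) Klf4 libraries of the same state shared 30.0% of their merged regions and libraries of different state 26.8%, a difference reached by 2 of 10 splits (exact permutation in this direction only, p = 0.2). That difference was −1.61 without asynchronous 1 and −1.05 without asynchronous 2.

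Klf4 signal from a small share of stem cells was examined in the mix of 10% stem cells and 90% neural progenitors. Its list held 1334 peaks of a median width of 58 bp, of which 1307 (98.0%) had q above 0.05 and 3.22% lay near a gene end. Only 0.920% of its 145035 numbered peaks were listed, all with a −log10 p of at least 5, and any further rule is unknown. Its recovery is therefore that of the list and not of all its signal. The mix recovered 13 of the 13982 asynchronous Klf4 regions (0.0930%, 95% Wilson interval 0.0543 to 0.159; 0.0283% after shifts), of which 10 were kept, 3 intermediate and 0 lost. Mitotic Klf4 lists of the same length recovered 8.74%, 7.97% and 9.11% of the regions. Of its own peaks, 0.975% lay in asynchronous Klf4 regions, against 76.0%, 76.8% and 74.0% of the peaks of the mitotic libraries. With peaks of −log10 q of at least 5, of which the mix had 3, recovery by the mix was 0.0141%.

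Whether Klf4, Oct4, Sox2 and H3K27ac differed in retention was compared through recovery per mitotic library. Mean recovery was 31.1% for Klf4, 44.2% for Oct4, 56.3% for Sox2 and 53.3% for H3K27ac. Both H3K27ac libraries lay above all 3 Klf4 libraries, and no comparison had enough libraries for a p under 0.05. H3K27ac exceeded Klf4 by 22.2 percentage points (exact permutation p = 0.2), Sox2 exceeded Klf4 by 25.1 (exact p = 0.3) and Oct4 exceeded Klf4 by 13.1 (exact p = 0.6). Oct4 and Sox2 differed by 12.1 (exact p = 0.667), Oct4 and H3K27ac by 9.12 (exact p = 1), and H3K27ac minus Sox2 was −2.94 (exact p = 1); 2 against 2 libraries cannot give a p under 0.333. With lists of equal length recovery was 48.4%, 47.2%, 56.6% and 65.0% in the same order, and the signs of Oct4 minus Klf4 (−1.22) and of H3K27ac minus Sox2 (8.48) turned. Both H3K27ac libraries (65.1% and 65.0%) then lay above every library of the 3 factors, of which the highest was 58.1%. Lists were of equal length within an antibody only: 3795 peaks for Klf4, 1246 for Oct4, 1940 for Sox2 and 30771 for H3K27ac. The rule for the asynchronous set also differed between antibodies. Overlap after shifts was 3.57% and 3.25% for H3K27ac, against at most 0.308% for the factors, so the antibodies were not compared on equal terms. Within project EC-EA-3702 mitotic lists overlapped 37.0% of asynchronous Klf4 peaks (36.3 to 37.8), 25.7% and 62.8% of Oct4 peaks, and 69.2% and 43.3% of Sox2 peaks. With pairs of lists of equal length these values were 54.6% for Klf4, 44.0% and 51.0% for Oct4 and 57.6% and 55.5% for Sox2.

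Peaks with the stronger signal in asynchronous cells were recovered in mitosis more often. Here recovery was counted over all peaks of each asynchronous list, also those seen in a single library, and averaged over lists. From the weakest to the strongest quintile of fold, mean recovery in mitotic libraries went from 14.7% ± 6.09 to 54.0% ± 18.8 for Klf4 (SD, n = 3), from 29.7% ± 22.2 to 72.5% ± 28.4 for Oct4 (SD, n = 2), from 36.6% ± 19.4 to 87.9% ± 9.12 for Sox2 (SD, n = 2) and from 18.7% ± 2.11 to 92.2% ± 1.29 for H3K27ac (SD, n = 2). Ranked by fold the quintile next to the weakest did not exceed it for Klf4, Oct4 or Sox2, whereas ranked by −log10 p it did for all 3 (15.4% against 10.6%, 30.6% against 24.3% and 38.4% against 33.0%). No test was made across quintiles.

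**Figure D3:**
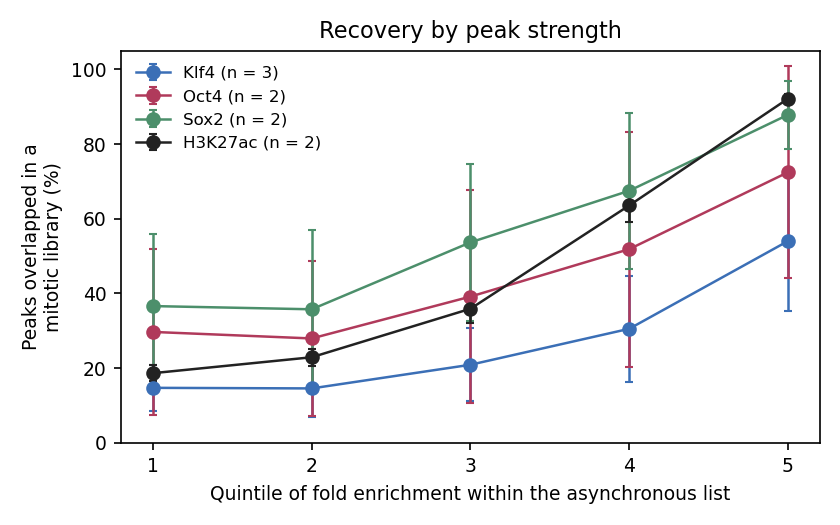
Percent of the peaks of asynchronous lists recovered in mitosis (vertical axis) by quintile of fold enrichment from weakest to strongest (horizontal axis) for each antibody. Points are means over mitotic libraries and bars SD. The strongest quintile stood highest for all 4 antibodies, from 54.0% for Klf4 to 92.2% for H3K27ac.

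Kept Klf4 regions more often carried active chromatin and the other pluripotency factors than lost ones. H3K27ac of asynchronous cells overlapped 85.5% of kept and 59.4% of lost Klf4 regions (odds ratio 4.02, 95% interval 3.63 to 4.46; Fisher's exact test, adjusted p = 2.39e-175), and mitotic H3K27ac 68.7% and 38.4% (3.52, 3.23 to 3.84; 6.66e-191). Oct4 was present at 12.1% of kept and 5.98% of lost Klf4 regions (2.16, 1.87 to 2.49; 1.22e-25) and Sox2 at 12.3% and 4.63% (2.90, 2.49 to 3.38; 2.93e-43). Of kept Klf4 regions 67.5% overlapped a kept H3K27ac region and 14.0% a lost one, and of lost Klf4 regions 37.4% and 15.9%. Each of these 4 odds ratios was above 1 in 9 of 9 pairs of an asynchronous and a mitotic library. Gene ends were near 44.5% of kept and 32.3% of lost Klf4 regions (1.68, 1.54 to 1.82; exact adjusted p = 8.4e-34), but within project EC-EA-3702 the shares were 37.8% and 39.0% (0.951, 0.891 to 1.02; exact p = 0.138), and the odds ratio was 1.06 without asynchronous 2 (adjusted p = 0.329) and 0.895 with −log10 q of at least 5. The odds ratio for Oct4 was 3.66 without asynchronous 1, and that for Sox2 7.09 without asynchronous 1 and 6.48 without asynchronous 2. Among Klf4 regions of similar strength the ratios were 3.23 for asynchronous and 3.10 for mitotic H3K27ac, 1.31 (1.11 to 1.55) for Oct4 and 1.95 for Sox2. Without both project EC-DG-3514 libraries the ratios were 2.18 for asynchronous and 1.95 for mitotic H3K27ac, with the 1 mitotic library left sufficient. Within project EC-EA-3702 the ratios were 2.68 for asynchronous and 2.204 for mitotic H3K27ac, 4.01 for Oct4 and 7.34 for Sox2.

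Kept Oct4 and Sox2 regions overlapped the other factor more often, and lay near gene ends less often, than lost ones. Most regions lay away from gene ends whether kept or lost. Sox2 overlapped 69.5% of kept and 12.1% of lost Oct4 regions (odds ratio 16.6, 13.2 to 20.8; Fisher's exact test, adjusted p = 1.48e-160), and Oct4 overlapped 54.4% of kept and 20.5% of lost Sox2 regions (4.63, 3.79 to 5.67; 3.08e-55). Klf4 was present at 51.5% against 25.8% of Oct4 regions (3.05, 2.53 to 3.69; 1.29e-31) and at 42.0% against 26.3% of Sox2 regions (2.03, 1.68 to 2.46; 2.18e-13). Asynchronous H3K27ac marked 68.3% of kept and 49.7% of lost Oct4 regions (2.18, 1.81 to 2.62; 1.17e-16) and 70.5% and 48.3% of Sox2 regions (2.56, 2.13 to 3.07; 6.86e-24), and mitotic H3K27ac 47.9% and 36.3% (1.62, 1.35 to 1.94; 1.95e-07) and 47.7% and 28.4% (2.295, 1.90 to 2.77; 1.37e-18). Gene ends were near 6.10% of kept and 17.6% of lost Oct4 regions (0.303, 0.220 to 0.418; exact adjusted p = 4.53e-15) and 4.11% and 7.81% of Sox2 regions (0.506, 0.346 to 0.738; 0.000432). With −log10 q of at least 5 these 2 ratios were 0.732 (exact adjusted p = 0.501) and 0.810 (exact adjusted p = 0.692). Without Oct4 mitotic 1, when a peak in mitotic 2 sufficed, the Oct4 ratios were 6.40 for Sox2, 1.67 for Klf4, 1.34 for asynchronous H3K27ac and 1.09 for mitotic H3K27ac (exact adjusted p = 0.270). Without Oct4 mitotic 2 they were 6.75 for Sox2 and 0.521 for gene ends, and without Sox2 mitotic 1 the ratio of Sox2 regions for Oct4 was 2.75.

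Kept H3K27ac regions lay near genes and carried Klf4 more often than lost ones. Gene ends were near 48.2% of kept and 17.4% of lost H3K27ac regions (odds ratio 4.41, 4.17 to 4.66), and Klf4 bound 41.0% and 19.8% (2.82, 2.67 to 2.98), Oct4 8.23% and 4.62% (1.85, 1.67 to 2.05) and Sox2 7.56% and 5.16% (1.50, 1.36 to 1.66). All 4 passed the adjusted threshold of 0.05. Among H3K27ac regions of similar strength the ratio was 2.198 (2.04 to 2.36) for gene ends and 1.08 for Klf4, and turned to 0.712 (0.619 to 0.819) for Oct4 and 0.511 (0.445 to 0.588) for Sox2. Away from gene ends the ratio for Klf4 at similar strength was 0.921 (0.842 to 1.01). With −log10 q of at least 5 the Sox2 ratio was 1.08 and no longer passed. Without asynchronous 1 the ratios for Oct4 and Sox2 were 2.83 and 2.57, and without asynchronous 2 that for Sox2 was 2.34.

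**Figure D4:**
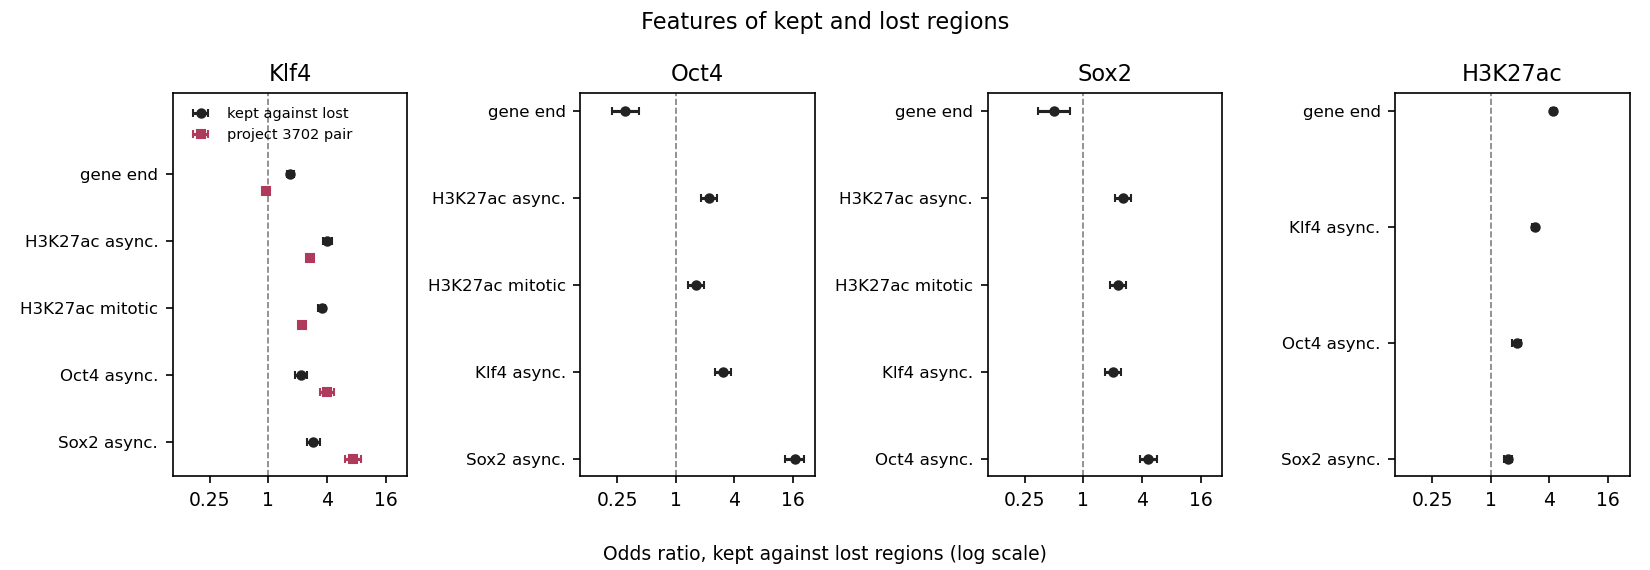
Odds ratios (horizontal, log axis) of features at kept against lost regions of each antibody, with 95% intervals; red squares in the Klf4 panel are the pair of libraries of project EC-EA-3702. The ratio for gene ends was above 1 for Klf4 (1.68) and H3K27ac (4.41) and below 1 for Oct4 (0.303) and Sox2 (0.506), and the project EC-EA-3702 Klf4 value was 0.951.

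Naive pluripotency genes kept bound regions more often than other bound genes for all 3 factors and for H3K27ac. A kept Klf4 region lay near 26 of 36 bound naive genes (72.2% against 42.3% of other bound genes; Fisher's exact test, adjusted p = 0.00566), including Nanog, Sox2, Esrrb and Tbx3, but not Dppa3, Gdf3, Dppa2, Dppa4, Dppa5a, Tfcp2l1, Tcl1, Utf1, Lifr and Nr0b1. For Oct4 it was 12 of 25 (48.0% against 20.9%; 0.0272): Sox2, Rif1, Lefty1, Lefty2, Pou5f1, Rest, Il6st, Gdf3, Dppa3, Nanog, Tfcp2l1 and Klf2. For Sox2 it was 19 of 25 (76.0% against 37.3%; 0.00123), all but Dppa5a, Fbxo15, Zfp42, Prdm14, Lin28a and Fgf4, and for H3K27ac 38 of 40 (0.0227), all but Lifr (chromosome 15, 7078861 to 7082569) and the nuclear receptor gene Nr0b1 (chromosome X, 86191606 to 86193403). Random genes matched on peak strength had kept regions in 66.8% (Klf4), 35.2% (Oct4), 59.4% (Sox2) and 95.9% (H3K27ac) of cases, and against these no naive list passed (permutation of matched lists, adjusted p = 1, 0.752, 0.561 and 1). The calls were also lost for Klf4 without asynchronous 1 (exact adjusted p = 0.0518), asynchronous 3 (0.116), mitotic 1 (0.102) or mitotic 3 (0.734, where list minus rest was 6.63 points), for Oct4 without mitotic 1 (0.0841) or chromosome 8 (0.0913), for Sox2 without mitotic 2 (0.209), and for H3K27ac without mitotic 1 (0.0566) or mitotic 2 (0.254). Within 2 kb the adjusted p was 0.211 for Klf4, 0.253 for Sox2 and 0.307 for H3K27ac, and with −log10 q of at least 5 it was 0.0739 for Klf4 and 0.736 for Sox2. Before any question of retention, naive genes were bound more often than other genes: 90.0% against 48.5% for Klf4 (Fisher's exact test, adjusted p = 6.63e-07), 62.5% against 11.6% for Oct4 (3.2e-13), 62.5% against 8.73% for Sox2 (4.56e-16) and 100% against 67.6% for H3K27ac (2.18e-06).

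Germ layer regulators, transcription factors that specify embryonic lineages, had a kept H3K27ac region less often than other genes. Of 11 marked genes 2, among them Tbx6, had a kept H3K27ac region (18.2% against 79.7% of other genes; Fisher's exact test, adjusted p = 0.000243), and genes without one included Gsc, Gata4, Cdx1, Msgn1, Cdx2, Neurog1 and Hoxb1. This did not mean that the mark was absent: 11 of 28 germ layer genes had an H3K27ac peak in each mitotic library (18 and 17 in the asynchronous ones), and 6, Gata4 among them, had a mitotic-only region. The difference also passed against genes matched on strength (55.8%; permutation of matched lists, adjusted p = 0.0187), without each H3K27ac library in turn, within 2 kb and within 50 kb, where list minus rest was −25.2 against −61.5 points. The strongest H3K27ac region linked to Tbx6 had the same percentile (98.7) as that of Aldoa in the glycolysis and energy list, so it may be shared. Klf4 was kept at 1 of 11 germ layer genes (9.09%; exact adjusted p = 0.122), Oct4 at 1 of 3 and Sox2 at 0 of 3. Feeder fibroblast genes, which encode matrix and contractile proteins, also had fewer kept H3K27ac regions (6 of 13, 46.2%; exact adjusted p = 0.0227; Sparc, Fn1, Tagln, Fstl1, Col1a1 and Lum), a difference that did not pass against genes of matched strength (61.1%; 0.684), within 2 kb (0.0556) or with −log10 q of at least 5 (0.0918). Klf4 was kept at 3 of 10 of them (exact adjusted p = 0.837), Oct4 at 1 of 3 and Sox2 at 2 of 3. The kept Sox2 genes, Col3a1 and Col5a2, had a region of the same percentile (93.3), which may be shared.

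Almost all marked cell cycle and chromatin genes had at least 1 kept H3K27ac region, but not all of their regions were kept. Linked H3K27ac regions numbered 64 kept and 34 lost for mitotic cell cycle genes. For G1 and S phase genes they numbered 70 and 21, and for chromatin regulators 79 and 32. All 32 marked mitotic cell cycle genes had a kept H3K27ac region (100% against 79.6%; Fisher's exact test, adjusted p = 0.00746), as did 31 of 32 G1 and S phase genes, all but Myc (96.9%; 0.0244), and 32 of 33 chromatin regulators, all but the Mediator gene Med12 (97.0%; 0.0227). None of these 3 lists passed against genes of matched strength (95.8%, 94.8% and 97.6%; permutation of matched lists, adjusted p = 0.684, 0.905 and 1). Without H3K27ac mitotic 2 their adjusted p were 0.0632, 0.213 and 0.171, and without mitotic 1 that of chromatin regulators was 0.0566. Within 2 kb G1 and S phase (0.0556) and chromatin regulators (0.148) did not pass. Sox2 was kept at 7 of 7 chromatin regulators (100% against 37.6%; exact adjusted p = 0.00594), among them Ino80, Trim28, Mtf2, Suz12, Jarid2 and Kdm5b. This call was lost without Sox2 mitotic 2 (0.253), within 2 kb (1), within 50 kb (0.205), with −log10 q of at least 5 (0.247) and against genes of matched strength (0.696). Klf4 was kept at 5 of 23 mitotic cell cycle genes (21.7%; exact adjusted p = 0.154), Aurkb, Birc5, Aurka, Fzr1 and Ube2c, at 10 of 23 G1 and S phase genes (1) and at 17 of 27 chromatin regulators (0.122). Oct4 was kept at 2 of 4, 1 of 4 and 5 of 9 genes of these lists, and Sox2 at 1 of 4 mitotic cell cycle genes and 1 of 1 G1 and S phase gene.

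The other gene groups did not pass for any antibody. H3K27ac was kept at 30 of 32 housekeeping genes, all but Pgk1 and B2m (93.8%; exact adjusted p = 0.0745), at 22 of 25 glycolysis and energy genes, all but Pgk1, Hk1 and Ldhb (0.455), at 22 of 32 LIF, Wnt and Bmp signalling genes (0.175; without one at Id1, Id2, Id3, Jak1, Jak2, Lifr, Cdx1, Bmp4, Sp5 and Lef1), at 13 of 19 primed pluripotency genes (0.307) and at 13 of 18 neural progenitor genes (0.430). Klf4 was kept at 13 of 22 housekeeping (0.291), 7 of 16 glycolysis (1), 10 of 26 signalling (1), 9 of 17 primed (0.837) and 9 of 18 neural genes (0.872). Oct4 was kept at 1 of 6 housekeeping, 1 of 6 glycolysis, 3 of 8 signalling, 2 of 8 primed and 2 of 7 neural genes, with adjusted p from 0.731 to 1. Sox2 was kept at 2 of 5, 1 of 4, 6 of 8 (75.0%; exact adjusted p = 0.218), 0 of 3 and 3 of 8 genes of these lists.

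**Figure D5:**
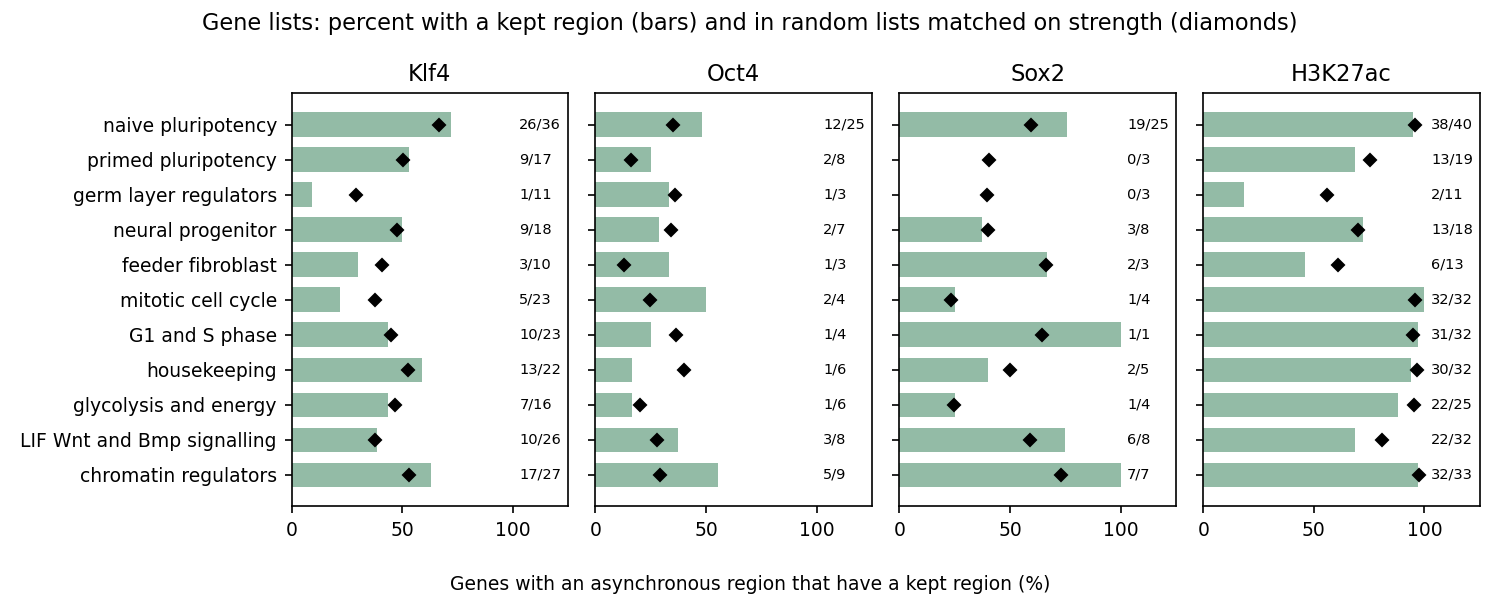
Percent of bound genes of each list with a kept region (bars; kept and bound counts printed beside them) per antibody, with random lists matched on peak strength (diamonds). For H3K27ac, germ layer regulators stood at 18.2% against 55.8% in matched lists, while naive pluripotency stood at 38 of 40 against 95.9%.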

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

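The run stratified by peak strength was planned but set as a test of the gene end result after that had been seen, and the test on projects was chosen after it, whereas the test on region width was set before its result. Each result here was picked out because the odds ratio of a nearby gene end, kept against lost regions, differed between a pair of antibodies by a chi-square test with 1 degree of freedom, in which regions are not independent replicates. The ratio was 1.68 for Klf4 and 0.303 for Oct4 (chi-square 102). Klf4 and Sox2 (0.506) differed with a chi-square of 36.8. Klf4 and H3K27ac (4.41) differed with a chi-square of 355. Oct4 and Sox2 differed with a chi-square of 4.08 (p = 0.0434). H3K27ac differed from Oct4 with a chi-square of 258 and from Sox2 with a chi-square of 123. The only group of 4 samples, the asynchronous inputs, had no peak list, so no library far from the others of its group was looked for, and no deposited list was left without use.

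Kept Klf4 regions lay near gene ends more often, and kept Oct4 regions less often, than lost ones. Stronger peaks at kept regions were argued against as the whole cause, since among regions of similar strength the ratios were 2.203 (1.99 to 2.44) for Klf4 and 0.261 for Oct4, and wider kept regions likewise, since the Klf4 ratio at the region midpoint was 1.62 (1.49 to 1.77). Within project EC-EA-3702, which holds all Oct4 libraries, the Klf4 ratio was 0.951 (0.891 to 1.02), so libraries of different projects may account for the Klf4 value above 1. It was 1.06 without Klf4 asynchronous 2, which is of another project, but higher without any other single library. Over pairs of an asynchronous and a mitotic library the Klf4 ratio was above 1 in 8 of 9, all but the pair of project EC-EA-3702. In that project the Klf4 pair still differed from Oct4 mitotic 1 and 2 (0.523 and 0.330; chi-square 15.3 and 78.4) and from Sox2 mitotic 1 and 2 (0.588 and 0.617; chi-square 8.35 and 6.21). Peaks near the calling threshold stay open too, since with −log10 q of at least 5 the ratios were 0.895 (0.758 to 1.06) for Klf4 and 0.732 (0.363 to 1.48) for Oct4 and the contrast was no longer seen, and a difference between the factors themselves stays open on a single pair of Klf4 libraries and was not tested further.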

How the results depend on the processing

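The runs without chromosome 8, without both Klf4 libraries of project EC-DG-3514, of Klf4 features within project EC-EA-3702 alone, at the region midpoint and with lists matched on strength and number of regions were chosen after the results had been seen; all others were planned. Depth was unknown, the kept share depended on list length and on the number of mitotic libraries required, and lists of few bound genes limited the gene group results. Of the alternatives for results that answer a comparison, 214 were counted as the same, 44 values moved, 25 calls ended and 9 results reversed. For single lists, named regions and the other differences between antibodies the numbers were 339, 2, 20 and 80, with 8 calls gained. A test was the same when it kept direction and side of the threshold, and a share or count when it stayed within a set spread. For kept shares this spread was the SD of recovery between mitotic libraries, 26.2 points for Oct4. Tests between libraries could not give a p under 0.05, so for them only the direction could change. An overlap of at least 50% of the shorter interval could not change the classes, since each peak lies wholly within the region merged from it, and these runs, included in the numbers above, show nothing. The cause was not tested, except that stricter peaks, shorter windows and left-out libraries leave fewer regions by construction.

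The kept share was 56.0% (Klf4), 63.8% (Oct4), 71.6% (Sox2) and 60.6% (H3K27ac) with any mitotic library as the requirement, and 47.6% (Klf4) and 57.8% (H3K27ac) with lists of equal length, where lost and mitotic-only regions numbered 832 and 491 (Klf4) and 6378 and 6401 (H3K27ac). For Klf4 it was 9.83% with −log10 q of at least 5, 45.3% with all 3 asynchronous libraries required, 14.8% with any 1 asynchronous library and 44.2% without both project EC-DG-3514 libraries, where the 1 mitotic library left sufficed. Recovery by the mix was 0.0141% with −log10 q of at least 5. At equal length Oct4 minus Klf4 turned to −1.22 points and H3K27ac minus Sox2 to 8.48. The Klf4 gene end odds ratio was 0.895 with −log10 q of at least 5, 0.974 without both project EC-DG-3514 libraries and 0.943 with regions merged from the project EC-EA-3702 libraries alone, against 0.951 for that pair over regions merged from all 6 libraries. With −log10 q of at least 5 the gene end ratio was 0.732 for Oct4 and 0.810 for Sox2, and that of Sox2 at H3K27ac regions 1.08. Stratified by strength the ratios at H3K27ac regions were 0.712 for Oct4 and 0.511 for Sox2. Ranked by −log10 p, strongest minus weakest quintile was 49.6 points for Oct4 and 77.2 for H3K27ac.

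The lists called numbered 1 (Klf4), 1 (Oct4), 2 (Sox2) and 6 (H3K27ac). Within 2 kb they were 0 for Klf4 and Sox2 and 2 for H3K27ac, within 50 kb 2 for Oct4, with −log10 q of at least 5 0 for Klf4 and Sox2, and without chromosome 8 0 for Oct4. Matched on strength they were 0, 0, 0 and 1, and matched also on number of regions 0, 0, 0 and 2. Naive pluripotency minus other genes, in points, was 22.5 (Klf4), 30.1 (Sox2) and 10.6 (H3K27ac) within 2 kb, 17.5 (Klf4) and 14.0 (Sox2) with −log10 q of at least 5, and 26.2 (Oct4) without chromosome 8. It was 5.47, 12.8, 16.6 and −0.897 matched on strength and 4.04, 12.9, 11.1 and −1.27 matched also on number, for Klf4, Oct4, Sox2 and H3K27ac.

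Differences of other lists that turned sign, in points, follow by setting. Matched on strength they were −1.29 for G1 and S phase, −2.85 for glycolysis and 0.578 for signalling (Klf4), −2.74 for germ layer, −5.71 for neural and −11.6 for G1 and S phase (Oct4), 1.45 for mitotic cell cycle, −10.2 for housekeeping and 0.220 for glycolysis (Sox2), and 2.47 for neural, −3.00 for housekeeping, −7.33 for glycolysis and −0.631 for chromatin (H3K27ac). Matched also on number they were −7.56 for G1 and S phase and −10.6 for glycolysis (Klf4), −1.73 for germ layer, −5.58 for neural and −3.93 for G1 and S phase (Oct4), 2.83 for mitotic cell cycle and −7.94 for housekeeping (Sox2), and 2.05 for neural, −2.77 for housekeeping, −6.72 for glycolysis and −0.244 for chromatin (H3K27ac). With −log10 q of at least 5 they were 15.7 for feeder, 9.37 for mitotic cell cycle, −0.362 for G1 and S phase, −4.54 for glycolysis and 3.82 for signalling (Klf4), −13.3 for primed, −13.3 for germ layer, −13.3 for G1 and S phase and 11.8 for housekeeping (Oct4), 4.84 for neural, −28.6 for feeder and −28.6 for G1 and S phase (Sox2), and 6.16 for neural (H3K27ac). Within 2 kb they were −1.40 for G1 and S phase, −1.40 for glycolysis and −9.75 for chromatin (Klf4), −14.8 for germ layer, 10.3 for glycolysis and −14.9 for chromatin (Oct4) and −29.7 for housekeeping (Sox2). Within 50 kb they were −5.49 for neural, −3.32 for glycolysis and 0.789 for signalling (Klf4), −1.05 for G1 and S phase, 9.24 for housekeeping and 5.89 for glycolysis (Oct4) and 1.17 for primed (H3K27ac). Without chromosome 8 signalling was 0.400 (Klf4).

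Where leaving out a library left 1 of its state, a peak in that library sufficed, so the requirement changed with the library. For Klf4 both libraries left of the state had to have a peak, a stricter rule than 2 of 3. Leaving out each library in turn gave kept shares from 13.0% to 43.3% for Klf4 (43.3% without asynchronous 2, 13.7% without mitotic 1 and 13.0% without mitotic 3), from 25.6% to 62.7% for Oct4 (62.7% without mitotic 1), from 43.3% to 69.1% for Sox2 (69.1% without mitotic 2) and from 35.8% to 55.7% for H3K27ac. The within minus between overlap of Klf4 lists ran from −1.61 (without asynchronous 1) to 8.72 and was −1.05 without asynchronous 2, the Klf4 gene end ratio from 1.06 (without asynchronous 2) to 2.15, and the mitotic H3K27ac ratio at Oct4 regions from 1.09 (without mitotic 1) to 1.77. Lists called numbered 0 to 2 for Klf4 (0 without asynchronous 1, asynchronous 3 or mitotic 3, 2 without mitotic 2), 0 to 2 for Oct4 (0 without mitotic 1), 0 to 2 for Sox2 (0 without mitotic 2) and 2 to 7 for H3K27ac (2 without mitotic 2). Naive pluripotency ran from 6.63 to 32.6 points (Klf4), 26.2 to 30.3 (Oct4), 22.1 to 36.2 (Sox2) and 8.69 to 18.3 (H3K27ac). For Klf4 the lists that turned sign ran from −6.31 to 15.1 (primed), −6.38 to 19.9 (neural), −14.2 to 8.50 (feeder), −1.51 to 10.7 (G1 and S phase), −26.5 to 3.36 (glycolysis), −12.6 to 5.89 (signalling) and −1.52 to 27.8 (chromatin). For Oct4 they ran from −8.11 to 3.00 (primed), −24.8 to 11.3 (feeder), −8.10 to 28.0 (mitotic cell cycle), −8.11 to 28.1 (housekeeping), −24.8 to 11.4 (glycolysis) and −8.11 to 15.5 (signalling), and for Sox2 from −40.3 to 33.9 (primed), −40.3 to 0.467 (germ layer), −2.78 to 21.4 (neural) and −26.3 to −0.270 (housekeeping). The H3K27ac neural list ran from −11.7 to 0.565.

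Pairing H3K27ac libraries by number (replicate block) gave a mean overlap of 44.7%, against 44.8% for crossed numbers, and the differences in calls of same-numbered libraries had a correlation of −0.0096 across regions, so the numbers were not taken as paired.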

Other observations

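Co-binding, chromosome shares, H3K27ac mitotic-only positions and the tests on list length, mitotic state, the H3K27ac share of chromosome 8 and weak mitotic peaks as the source of most regions were chosen after the results had been seen; the tests on 4 equal segments of chromosome 8, on cell type lists, the fall in number without weak peaks, project EC-DG-3514 peaks and splits of the libraries were set before theirs.

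Sites bound by several pluripotency factors were kept in mitosis at a higher share than sites bound by 1 of them. Klf4 regions that also carried Oct4 and Sox2 were kept in 46.1% of 503 cases (95% Wilson interval 41.8 to 50.5), those with Sox2 only in 45.8%, those with Oct4 only in 36.1%, and those with neither in 24.9% of 12361. Oct4 regions with Klf4 and Sox2 were kept in 60.1%, with Sox2 only in 39.9%, with Klf4 only in 19.9% and with neither in 8.27%. Sox2 regions with both partners were kept in 62.2%, with Oct4 only in 51.7%, with Klf4 only in 38.7% and with neither in 27.8%. Strength differed too: the median percentile of Oct4 regions was 70.0 with both partners and 40.1 with neither. At 123 regions all 3 factors were kept, of which 116 (94.3%) had H3K27ac in asynchronous and 96 (78.0%) in mitotic cells. They included regions by Lefty2, a Nodal antagonist (chromosome 1, 180888548 to 180889603), Nanog (chromosome 6, 122707269 to 122707642), Pou5f1, Sox2, Klf2 and Rif1, a telomere and replication timing factor of stem cells.

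H3K27ac regions found in both mitotic libraries and in no asynchronous one lay farther from gene ends than kept or lost ones. Their median distance to a gene end was 23.0 kb, against 3.21 kb for kept and 14.1 kb for lost regions, while 49.1% lay inside a gene span, against 62.5% of kept and 49.4% of lost regions. Such a region lay within 20 kb of 12 of 34 chromatin regulators (35.3% against 17.6% of other genes; Fisher's exact p = 0.0118, adjusted p = 0.130, not past the threshold), among them Arid1a, Brd3, Crebbp, Eed, Ep300, Kdm5b, Med1, Smarcc1, Smc1a, Smc3 and Suz12. Among H3K27ac regions away from gene ends and of similar strength, those with Sox2 were kept less often than those without (odds ratio 0.734, 0.639 to 0.844), and the ratio was 0.864 (0.747 to 1.00) for Oct4 and 0.921 (0.842 to 1.01) for Klf4. Near gene ends the ratios were 0.433 (0.240 to 0.780) for Sox2, 1.36 (0.892 to 2.08) for Oct4 and 1.34 (1.17 to 1.53) for Klf4. On the X chromosome the mitotic share of peaks was 2.35-fold the asynchronous one in Oct4 mitotic 2 but lower in Oct4 mitotic 1 (1.12% against 1.40%), and 1.61-fold and 1.43-fold in the Sox2 libraries and 1.16-fold in Klf4 mitotic 3, where asynchronous 3 of the same project had 1.36% against 1.37%. It was 0.469-fold and 0.555-fold in Klf4 mitotic 1 and 2 and 0.850-fold and 0.843-fold in the H3K27ac libraries.

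Chromosome 8 held more peaks in the mitotic libraries of project EC-DG-3514 than in asynchronous ones: 9.30% and 9.72% of Klf4 peaks against 5.12%, 5.42% and 6.93%, and 6.36% and 6.56% of H3K27ac peaks against 4.82% and 4.85%. Extra copies of chromosome 8 in those cultures, a change known from stem cell culture, are a candidate explanation. For 4 equal segments of the chromosome, 16 of 16 values lay above every asynchronous library of the antibody. As the share of the whole chromosome was raised, this shows an excess along its length but not its cause. In Klf4 mitotic 3 of project EC-EA-3702, 2 of the 4 segments lay above every asynchronous Klf4 library. Amplification of a single locus was argued against by all 4 libraries of project EC-DG-3514 having at least 3 raised segments. Mitosis itself was argued against for Klf4 only, by a single pair of libraries within project EC-EA-3702. The ratio of that pair was 0.918 (0.831 to 1.01), against 1.34 (1.22 to 1.48) and 1.40 (1.25 to 1.57) in Klf4 mitotic 1 and 2 over the same asynchronous 3 library. In that project the Oct4 ratios were 0.832 and 0.816. The Sox2 ratios were 1.13 (0.935 to 1.36) and 1.08 (0.856 to 1.36), with intervals that reach 1.34. H3K27ac had no library in that project, so mitosis stays open for its excess. Shorter lists were argued against for H3K27ac, where the highest asynchronous share at equal length was 4.93% (4.69 to 5.18), but cannot be told apart for Klf4, where it was 8.27% (7.44 to 9.19) in asynchronous 3, because that interval reaches those of the mitotic libraries at 10.0% and 9.72%. Of Klf4 regions on chromosome 8, 38.9% were kept, against 26.1% on all other chromosomes.

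The 5781 mitotic-only H3K27ac regions may reflect the state, the project or other cells, and these cannot be told apart. Extra copies of chromosome 8 were argued against as their main source, since 7.94% (7.27 to 8.66) lay there. Feeder fibroblasts or neural cells stay open: the odds ratio of a mitotic-only region was 0.780 (0.270 to 2.25) for 28 feeder genes, with 4 hits (among them Cd44, Col5a1 and Pdgfra; none at Col1a1 or Fn1), and 0.814 (0.281 to 2.35) for 27 neural genes, intervals too wide to decide, while 13 and 18 genes of these lists had asynchronous H3K27ac; labels name no sort beyond the shake-off. Weak mitotic peaks were argued against as the source of most, since 64.3% (63.0 to 65.5) had a peak with −log10 q of at least 5 in both mitotic libraries. A part from weak peaks stays open. With that threshold in all lists and classes formed anew, mitotic-only regions went from 5781 to 4273, a net fall of 26.1%. Kept regions had a net fall of 27.3%. The asynchronous lists were cut as well, so regions could also become mitotic-only, and the comparison of these falls cannot decide. The share of Klf4 peaks in the mitotic-only H3K27ac regions was 0.521% (0.389 to 0.699) in mitotic 3 of project EC-EA-3702. It was 0.921% (0.705 to 1.20) and 0.606% (0.404 to 0.908) in mitotic 1 and 2 of project EC-DG-3514. In asynchronous 1, 2 and 3 it was 0.634%, 0.723% and 0.766%. Only mitotic 1 had an interval above that of mitotic 3, so the project was not separated from mitosis.

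In the 6 Klf4 libraries, 6253 regions had peaks in at least 2 libraries of a state and none of the other, 6156 of them asynchronous and 97 mitotic. This was reached by 1 of the 10 splits into 3 and 3, the real one, and the highest of the other splits gave 4582, but with 10 splits no share under 0.05 can be had. The asynchronous lists were the 3 longest, so list length largely fixed this outcome and it says nothing of the state by itself. With lists of equal length 832 and 491 regions were lost and mitotic-only, and another split had a larger within minus between overlap than the real one (6.97 against 3.22).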
